A study of Mus musculus with 2 samples.

How the data were processed

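RNA from 1 Empty NP library and 1 FuOXP NP library was sequenced as 75-base paired-end reads, per the labels. The submitters' processing notes name STAR 2.6.1a, Cufflinks 2.2.1 and Cuffdiff with the mouse build GRCm38, without saying which made the table. The authors deposited TPM values in 1 column per group, each relative to the length-scaled total of its library. The columns summed to 1001107 in Empty NP and 1000649 in FuOXP NP. The annotation and any removal of ribosomal RNA are not given in the sources used here. TPM values are relative, so a row that takes a larger part of 1 library lowers all others in it.

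Of 53927 rows, 22240 had no gene symbol and 26 had a symbol turned into a date by spreadsheet software. Those were left out of gene comparisons and kept in the totals. Where adjacent rows held the same pair of values under different symbols (54 rows) they were counted once, and of rows under a repeated symbol the highest was kept, which left 26601 genes. Exon lengths, positions and overlaps were taken from GENCODE vM21 for the 23908 genes whose symbol matched. Besides the overlaps given with the results, exons of Ano6, Cd74, Clec9a, Lipe, Nptn, Plin4, Rpph1, Tbp and Timm8b overlap another annotated gene, so their reads may be shared.

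Differences were computed as log2((FuOXP NP + 1)/(Empty NP + 1)), which understates the change of low genes, among genes with a mean of 1 TPM or more. With 1 library per group there is no test. Genes were called apart at a 2-fold difference. The median of each fixed list with at least 5 measured members was set against 10000 random lists of the same size, matched in 20 equal bins of mean log2(TPM + 1), and a list was said to stand apart at a percentile of at most 2.5 or at least 97.5. Genes share regulation and these percentiles describe the 2 libraries only. Older symbols in lists were matched through unambiguous RefSeq synonyms.

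Reads were recovered as TPM times exon length divided by the value of 1 read on 1000 exon bases, 3.56 TPM in Empty NP and 1.91 TPM in FuOXP NP. Of genes under 10 reads, 81.0% in Empty NP and 80.9% in FuOXP NP came out within 0.01 of a whole number, where chance gives 2%. Independently of length, 88.2% of the 9010 genes above 0 in both libraries had a TPM ratio that whole reads with at most 30 in Empty NP give, against 0.0999% after each ratio was multiplied by a fixed irrational number. A recovered unit may be a read or a read pair. The recovered numbers are far below the read numbers in the labels, and the reason is not given in the sources used here. They were used for intervals and for added alternatives, not for the planned results. Intervals of a TPM ratio were exact 95% Clopper-Pearson intervals of the share of reads, put on the TPM scale.

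The genes named were fixed by rule before the data were examined: Xkr8 and the measured scramblase and flippase list, the 12 highest and 12 lowest log2 differences among genes with a mean of 10 TPM or more without names that start with Gm and a digit, end in Rik or are clone names (placeholder LOC names were kept), up to 4 members per list with the largest differences, the 5 most abundant genes per library, and abundant members of cell type lists. The steps were tested on simulated data at these read numbers, for FuOXP NP against Empty NP. In these data 200 genes were changed one by one, of which 199 passed the filter. In addition, 2 lists of 15 genes were moved, among 5328 genes that passed it. Only genes at 5 TPM or more in Empty NP were simulated, so the rates that follow do not cover genes at lower levels. Of genes raised by 2 log2 units 98% passed 2-fold relative to the median gene, and of those raised by 3 units 100%. Of genes lowered by 2 units 83.7% passed and of those lowered by 3 units 76%. The cause of these lower shares was not tested. Of unchanged genes 9.96% passed by counting noise. Of 200 unmoved lists 8% fell outside the middle 95%.

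Alternatives planned beforehand were pseudocounts of 0.1 and 5 TPM, centring on the median gene, rescaling without the 20 most abundant rows, no filter, a mean of 5 TPM or more, 10 bins, lists without their most extreme member, and 100 rather than 20 abundant rows. Alternatives on members above 0 in both libraries, genes without exon overlap, recovered reads, at least 20 reads, and matching on the log2 of the mean TPM or on the Empty NP level alone were added after seeing the data. Matching on the log2 of the mean TPM was run first by mistake, before the matching fixed beforehand. Leaving out replicates was not possible with 1 library per group. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.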

Results

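The data were 2 RNA sequencing libraries from mouse tumours. CT26 cells, a colon carcinoma line from the BALB/c strain, were grown under the skin of BALB/c mice. Mice with tumours of about 200 mm3 received either empty nanoparticles (Empty NP) or nanoparticles carrying FuOXP (FuOXP NP), a conjugate of the drugs 5-fluorouracil and oxaliplatin. They were injected into a vein 3 times, once every 5 days, with 10 mg/kg of FuOXP in the drug group. Tumours were taken 24 hours after the last injection. The labels give 3 mice per group but the data hold 1 library per group, and they do not say whether the 3 tumours were pooled. No difference below therefore has a replicate check, and no p-value is given. The words higher and lower describe these 2 libraries only.

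The values were TPM, transcript abundances scaled to the same total in each library, for 53927 rows, of which 14761 were above 0 in Empty NP and 12321 in FuOXP NP. Of these rows, 22240 carried no gene symbol, and they held 62.9% of the summed TPM in Empty NP and 71.3% in FuOXP NP. The labels give 73 M to 77 M reads per sample. The low TPM values lay on steps of 1 read divided by the exon length of the gene, which allowed read numbers to be recovered for genes with a symbol and an annotated exon length. These summed to 448402 in Empty NP and 935308 in FuOXP NP, of which Lars2 alone took 129679 and 724582. The median gene above 0 rested on 6 reads in Empty NP and 4 reads in FuOXP NP. A gene listed at 0 is described as such and not as absent. Intervals below are exact 95% Clopper-Pearson intervals on recovered reads and cover counting error only.

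The comparison of FuOXP NP with Empty NP asks which transcripts differ in tumours after the drug-loaded particles, with Xkr8, a scramblase that exposes phosphatidylserine on the surface of dying cells, as the gene named in the series title. Xkr8 was listed at 0.113 TPM in Empty NP and 93.4 TPM in FuOXP NP. Relative to other genes of similar level, skeletal muscle transcripts were low in FuOXP NP and ribosomal protein genes were high. As deposited, the median of the ribosomal protein genes was also lower, at -0.82. On the same relative scale, other lists held less firmly or rested on few reads. Genes of antigen presentation on major histocompatibility complex (MHC) class I were low by their list median. Stress response genes, histones and erythroid and platelet markers were high by their list medians. The typical gene itself was lower in FuOXP NP, where a few rows held most of the summed TPM.

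The 20 most abundant rows held 47.3% of the summed TPM in Empty NP and 81.8% in FuOXP NP. A single row with no symbol held 14.4% and 47.9%. Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, stood at 4.16% and 12.5% of the total. The deposited values do not tell whether the reads listed under Lars2 came from its messenger RNA. The abundant non-coding RNA Eyelinc18 was almost equal, at 47911 and 48431 TPM, and Rpph1, the RNA part of ribonuclease P, was listed at 1474 and 4222 TPM. The 76 ribosomal protein genes together made up 1.21% and 0.802%. No mitochondrially encoded gene had a symbol in the table, so their share was not computed.

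Among the 9488 named genes with a mean of 1 TPM or more, the median log2 difference, FuOXP NP minus Empty NP on the log2(TPM + 1) scale, was -1.44, or 2.71-fold lower. As deposited, 222 genes were at least 2-fold higher and 6618 at least 2-fold lower. With differences centred on the median gene, the split was 1197 higher and 1157 lower, and with the 20 most abundant rows left out and both libraries rescaled it was 1025 higher and 2886 lower. Differences are therefore also given relative to the median gene. Of the genes 2-fold above the median gene, 206 had at least 20 recovered reads in both libraries together, as had 449 of those below it. Counting intervals were set against another centre, the median of the 1423 genes with at least 50 reads, 3.20-fold lower. They lay wholly beyond 2-fold of it for 54 genes above and 68 below, out of 3280 genes with at least 20 reads.

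**Figure D1:**
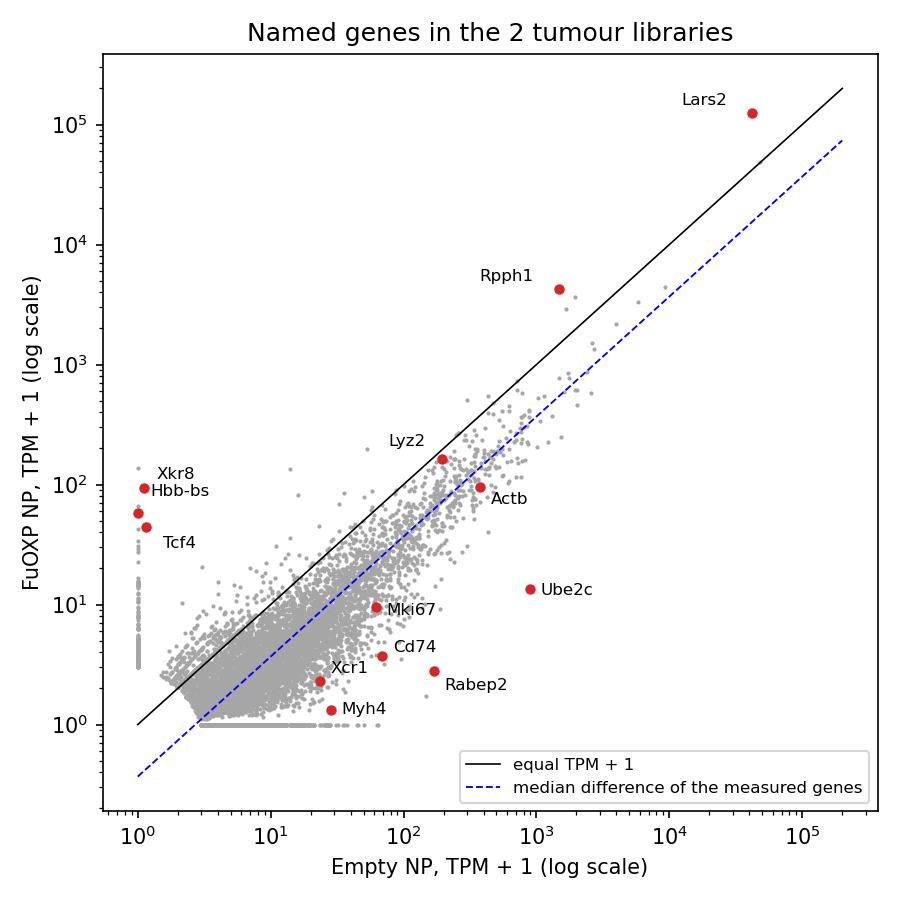
TPM + 1 of each named gene with a mean of 1 TPM or more in Empty NP (horizontal, log scale) and FuOXP NP (vertical, log scale), 1 library per group, with the line of equal values and the median difference of -1.44 dashed. Most genes lie below the line of equal values, Xkr8 and Tcf4 lie far above it, and Ube2c, Rabep2 and Myh4 lie far below the dashed line.

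Xkr8 lies on the minus strand of chromosome 4 from 132724897 to 132732546 (GRCm38, GENCODE vM21), is protein coding, and has exons that overlap no other annotated gene. Its log2 difference was 6.41, or 7.85 relative to the median gene, and it ranked 2 among the 2426 named genes with a mean of 10 TPM or more. The log2 value depended on the pseudocount and was 8.78 with 0.1 TPM and 4.27 with 5 TPM, as the Empty NP value was close to 0. A single read at Xkr8 would be 0.826 TPM in Empty NP, so the listed value was below that of 1 read. By the annotated exon length the values came to 0.137 and 211.17 reads. The ratio of a gene's TPM values does not depend on its length, and whole reads allow certain ratios only. Among 6607 genes above 0 in both libraries and under 20 Empty NP reads, Xkr8 and the transcription factor gene Tcf4 were the 2 whose ratio needed over 3 times as many whole Empty NP reads as the exon length gave. This rule was set after seeing the data, and 6 genes departed at 2 times and 10 at 1.5 times, with Xkr8 and Tcf4 among them. Tcf4 (chromosome 18, 69343356 to 69689079) was listed at 0.162 TPM in Empty NP and 43.3 TPM in FuOXP NP. No whole read number or counting interval can be given for these genes.

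Of the other 11 measured scramblases, flippases and partner proteins, 10 were lower in FuOXP NP as deposited. The remaining one, Plscr2, was at 1.12 and 1.20 TPM on 1 and 2 reads. With Xkr8 included, 9 members lay above the median gene and 3 below it. The list median was -0.93, and 0.51 relative to the median gene, at percentile 94.6 of 10000 random lists matched on expression, so the list did not stand apart. Ano6, a calcium-activated scramblase, was at 8.21 and 1.35 TPM on 26 and 8 reads. That is 6.07-fold lower (2.67 to 15.5), an interval that holds the 3.20-fold of the typical gene with at least 50 reads. Bsg and Nptn, which encode partner proteins of Xkr8, were at 33.4 and 5.77 TPM in Empty NP and 18.9 and 4.02 TPM in FuOXP NP. Tmem30a, the flippase subunit, had a log2 difference of -1.07 as deposited and lay 0.37 above the median gene.

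Of 50 gene lists fixed before the data were examined, 42 had at least 5 measured members. Of these, 2 lay at or below percentile 2.5 and 7 at or above the matching upper limit. At the nominal 5%, 2.1 would lie outside. In data simulated from genes at 5 TPM or more in Empty NP only, 8% of unmoved lists did so. MHC class I antigen presentation had a median of -2.10, and -0.66 relative to the median gene, at percentile 1.26, with 13 of 15 members below the median gene. H2-T23 was 14.2-fold lower (5.58 to 46.2), H2-K1, a classical class I heavy chain, was 5.87-fold lower (2.42 to 16.3), and Psmb9, an immunoproteasome subunit, was 6.46-fold lower (3.43 to 13.1), against 3.20-fold for the typical gene with at least 50 reads. The interval of H2-K1 reached below that typical value. Pooled over the list, the reads were 627 and 309, 3.79-fold lower (3.30 to 4.36). Exons of Psmb9 overlap those of Tap1, and without genes that overlap another the list lay at percentile 19.3. It also lay within the middle 95% on recovered reads, at 4.29, and when matched on the log2 of the mean TPM or on the Empty NP level, at 3.33 and 7.20, and these alternatives were chosen after seeing the data.

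Several immune lists had low medians without standing apart. Pan-leukocyte markers lay at percentile 8.93, with 4 members above and 5 below the median gene, and ran from 4.02 to 52.2 over the alternatives. Their pooled reads were 131 and 53, 4.61-fold lower (3.33 to 6.47). The interferon gamma response lay at percentile 3.00, with 13 of 17 members below the median gene. Its guanylate-binding protein genes Gbp3 and Gbp4 were 16.8-fold (6.02 to 65.0) and 19.1-fold (6.93 to 73.6) lower, and Cxcl9, a T cell attracting chemokine, was 11.2-fold lower (3.27 to 59.4). Exons of Gbp4 overlap those of Gbp8 and Gbp9, and without genes that overlap another the list lay at percentile 22.4, an alternative chosen after seeing the data. MHC class II antigen presentation lay at percentile 10.7, with 3 members above and 3 below the median gene, but ran from 3.93 to 73.3 over the alternatives. Its most extreme member Cd74, the invariant chain, was at 68.2 TPM in Empty NP and 2.71 TPM in FuOXP NP, while H2-Ab1, at 6.53 and 2.33 TPM, lay above the median gene. T cell markers lay at percentile 2.82 over 6 measured members, of which 3 were listed at 0 in FuOXP NP. Cd247 alone held 498 of the 514 reads of the list in Empty NP and 165 of 170 in FuOXP NP. Its exons overlap those of Pou2f1 and Gm16565, so its reads may be shared. Dendritic cell markers lay at percentile 26.7, with 4 members above and 5 below the median gene, but ran from 0.10 to 61.7 over the alternatives. Their pooled reads were 112 and 30, 6.97-fold lower (4.62 to 10.8). Xcr1, Clec9a and Zbtb46, markers of conventional dendritic cells, had 28, 23 and 30 reads in Empty NP and 3, 3 and 2 reads in FuOXP NP. Macrophage and monocyte markers lay at percentile 80.9, with 10 members above and 6 below the median gene. Their pooled reads were 352 and 363, 1.81-fold lower (1.56 to 2.10), beside 3.20-fold for the typical gene. Lyz2 and Apoe were near equal as deposited, at 194 and 68.3 TPM in Empty NP and 163 and 66.0 TPM in FuOXP NP. Relative to the median gene they lay 1.19 and 1.39 above it.

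Mitotic genes lay at percentile 8.51, with 17 of 21 members below the median gene. The proliferation marker Mki67 was 7.14-fold lower (5.11 to 10.1) on 172 and 45 reads, and Bub1b, a spindle checkpoint kinase, was 11.8-fold lower (3.48 to 62.4). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, was at 900 TPM in Empty NP and 12.5 TPM in FuOXP NP, but its exons overlap those of the muscle gene Tnnc2, and the deposited values do not tell reads of the 2 genes apart.

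Lists with high medians relative to the median gene included cytosolic ribosomal proteins, at 0.62 with 25 of 28 members above the median gene and percentile 100, although their median as deposited was -0.82. The integrated stress and unfolded protein response was at 0.51 with 14 of 18 members above the median gene, at percentile 99.3, and at percentile 95.1 with a pseudocount of 5 TPM. Its members Ddit3, a stress-induced transcription factor, and Sdf2l1 went the other way, at 104 and 16.1 TPM in Empty NP, with Ddit3 at 12.3 TPM and Sdf2l1 listed at 0 in FuOXP NP. The p53 targets were at 0.56, at percentile 98.9, with 15 of 21 members above the median gene. Members far below it included Ckap2 and Ccng1, 12.6-fold (4.39 to 49.6) and 10.6-fold (3.06 to 56.3) lower. The pooled reads of the list were 306 and 170, 3.36-fold lower (2.78 to 4.08), beside 3.20-fold for the typical gene. Over members with a mean of 5 TPM or more the p53 list lay at percentile 7.25, so its direction turned with the filter. Replication-dependent histones were at 0.47 and percentile 98.4, with 11 of 16 members above the median gene, and at percentile 94.9 with a pseudocount of 5 TPM. Of the members, 5 lay at least 2-fold above the median gene and 4 at least 2-fold below it. H2ac8 and H2ac6 went the other way, at 23.2 and 22.4 TPM in Empty NP and listed at 0 in FuOXP NP. No read numbers were recovered for this list.

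Markers of other tissues moved with the groups. Skeletal muscle markers had a median -1.56 relative to the median gene, at percentile 0 of random lists, and 11 of 14 measured members were listed at 0 in FuOXP NP. Myh4, a fast myosin heavy chain, was at 27.2 and 0.317 TPM on 46 reads and 1 read. Tnnt3 and Acta1 were at 22.5 and 16.2 TPM in Empty NP and listed at 0 in FuOXP NP. Erythroid and platelet markers had a median of 1.87 as deposited, and 3.31 relative to the median gene, at percentile 100. Hbb-bs, an adult beta globin, was listed at 0 in Empty NP and at 57.1 TPM in FuOXP NP. It held 23 of the 41 FuOXP NP reads of the list. Alas2, the first enzyme of erythroid haem synthesis, went the other way at 26 and 10 reads, 4.85-fold lower (2.26 to 11.3), and its exons overlap those of Apex2. The pooled reads of the list were 31 and 41, 1.41-fold lower as deposited (0.856 to 2.31). Neutrophil markers lay at percentile 99.9 over 5 measured members, and S100a9 rested on 4 reads in FuOXP NP and was listed at 0 in Empty NP. Without its most extreme member that list lay at percentile 82.7. Adipocyte markers lay at percentile 99.8 by their median, while their pooled reads went the other way, at 122 and 23, because Lipe and Plin4 were 28.5-fold (10.6 to 108) and 14.9-fold (6.79 to 38.8) lower. Over members above 0 in both libraries, an alternative chosen after seeing the data, the muscle, erythroid, neutrophil and adipocyte lists had fewer than 5 members and gave no percentile.

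**Figure D2:**
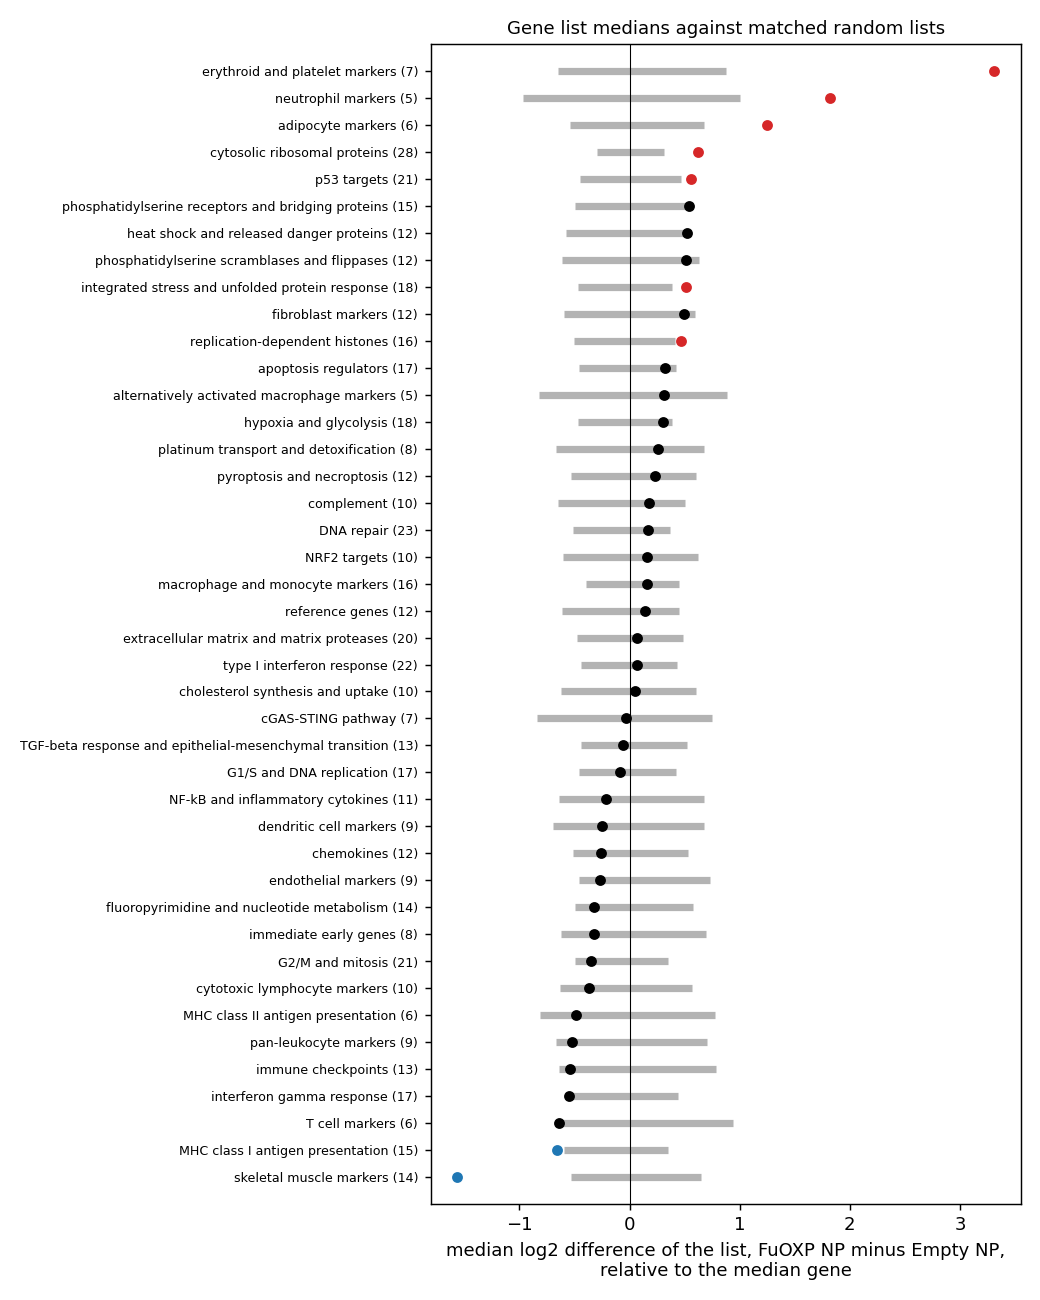
Median log2 difference of each of 42 gene lists, FuOXP NP minus Empty NP, relative to the median gene (points; measured members in brackets), with the middle 95% of 10000 random lists matched on expression (grey bars), 1 library per group. Skeletal muscle and MHC class I lie below their bars (blue), 7 lists lie above them (red), and the remaining lists lie within them (black).

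The extremes of the ranking among genes with a mean of 10 TPM or more held many low read numbers. Of the 12 highest, 6 carried placeholder LOC names, and of the other 6, 4 were listed at 0 in Empty NP, among them Rny3 on 3 reads and Timm8b on 6 reads in FuOXP NP, besides Hbb-bs. Of the 12 lowest, 1 carried such a name, and of the other 11, 9 were listed at 0 in FuOXP NP, among them Mrgpra1 on 15 reads and Trir on 11 reads in Empty NP. Rabep2, at 169 and 1.79 TPM, overlaps the muscle gene Atp2a1 in its exons.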

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

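The tests on Xkr8 against the median gene, on its exon length, on the share of genes off whole reads and on the percentile of the muscle markers were chosen after the result was seen, and the other tests were written before. The first replaced a test written beforehand on rescaling, which could only raise the Xkr8 difference. The last was changed 2 times with the values known: from the marker list to a second muscle list, which decided nothing, and back to the marker list over all its settings. Rows with no gene symbol lay outside the gene comparisons and held 71.3% of the summed TPM in FuOXP NP against 62.9% in Empty NP. The largest of them held 47.9% of the FuOXP NP total against 14.4% in Empty NP. The table gives no name for it.

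The median gene was lower in FuOXP NP, with a log2 difference of -1.44. A candidate explanation is that a few rows took most of the total. Without the 20 most abundant rows the median was -0.355, closer to 0 than -0.5 and short of the -0.25 set beforehand. This value cannot tell how much of the shift stays open, because the pseudocount weighs less on rescaled values. Without a pseudocount, leaving those rows out raised each remaining log2 ratio by 1.496. The median log2 ratio of the 1423 genes with at least 50 reads was -1.677 as deposited. For these genes most of the shift therefore goes with those rows, and a smaller part stays open. Whether the drug or the library preparation raised those rows was not tested with 1 library per group.

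Xkr8 was 6.41 log2 units higher in FuOXP NP. The scaling of the libraries does not account for it, since 1 factor for a library moves all genes alike and Xkr8 lay 7.85 above the median gene, or 4.998 with a pseudocount of 5 TPM. A different exon length does not account for it either, provided that both values came from whole reads and 1 common length. Under that condition the ratio of both Xkr8 values does not depend on length. It needed at least 25 Empty NP reads, 182.3 times the number the annotated length gives. Values made in another way than those of the other rows remain a candidate explanation, since 0.03% of the 6607 comparable genes, Xkr8 and Tcf4, needed over 3 times as many whole reads as their length gave. After every ratio was multiplied by a fixed irrational number all 6607 did. How these values arose is not known, and an effect of FuOXP on Xkr8 was not tested and stays open.

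Skeletal muscle markers were low in FuOXP NP, and 0 of the 14 measured ones stand in another list. A general loss of reads at this expression level is a candidate explanation. It is not decided here, because the test was chosen with the values known. The values show only that the marker list, fixed before the data were examined, was low beside genes of similar level. That list lay at or below percentile 0.24 of matched random lists in its 12 settings, matching on the Empty NP level among them. A second list of muscle genes was at or below 2.5 in 6 of 9 settings only, with a main value of 2.21 and a highest of 17.3. Muscle in the Empty NP tissue remains possible. The second list had a median of -0.54 relative to the median gene, between the bounds of -1 and -0.25 set beforehand. This value cannot decide the question, because the bound of -1 was out of reach. Most members stood at 2.36 to 3.94 TPM in Empty NP, where even a fall to 0 stays above -1 with the pseudocount used. The pooled reads of the second list were 146 in Empty NP and 20 in FuOXP NP, 13.6-fold lower (8.51 to 22.97). The 4 measured genes whose exons overlap a muscle gene all lay at least 2-fold below the median gene, as did 1157 of all 9488 measured genes. Among these 4, Ube2c and Rabep2 also stand among the 12 lowest genes of the ranking of these data. The count is therefore no independent evidence for muscle. An effect of the drug on muscle was not tested.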

How the results depend on the processing

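The alternatives on members above 0 in both libraries, exon overlap, recovered reads, at least 20 reads and matching on the log2 of the mean TPM or on the Empty NP level were chosen after seeing the data. No paired analysis was possible because each group has 1 library. Genes at least 2-fold higher numbered 222 and lower 6618. They were 70 and 3171 with a pseudocount of 5 TPM, 1197 and 1157 when centred, 1025 and 2886 when rescaled, 55 and 3315 at a mean of 5 TPM or more, and 9 and 2634 with at least 20 reads. With no filter 468 were higher. The Xkr8 log2 difference was 8.78 with a pseudocount of 0.1 TPM, 4.27 with 5 TPM, 7.85 when centred and 8.68 when rescaled, so its size depended on these choices and its direction did not. The 100 most abundant rows held 61.11% in Empty NP and 87.64% in FuOXP NP.

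Centring cannot move a list percentile. Ribosomal proteins stood apart under each alternative, and skeletal muscle under each one that left it 5 members. With a pseudocount of 0.1 TPM, p53 targets moved to percentile 94.47 and dendritic cell markers to 0.15. With 5 TPM, phosphatidylserine receptors moved to 99.26, heat shock proteins to 99.11, immune checkpoints to 0.98, the integrated stress response to 95.14 and histones to 94.92. After rescaling, p53 targets moved to 88.69 and dendritic cell markers to 0.48. With no filter the interferon gamma response moved to 2.09. At a mean of 5 TPM or more p53 targets turned to 7.25 over 5 members. With 10 bins the interferon gamma response moved to 2.43 and T cell markers to 2.36. Without the most extreme member phosphatidylserine receptors moved to 97.98 and neutrophil markers to 82.65. Over members above 0 in both libraries p53 targets moved to 96.87. Without overlapping genes the integrated stress response moved to 94.74 and MHC class I to 19.28. On recovered reads p53 targets turned to 38.51, MHC class I moved to 4.29, hypoxia and glycolysis to 98.34 and dendritic cell markers to 0.10. Matched on the log2 of the mean TPM, heat shock proteins moved to 98.66, MHC class I to 3.33, immune checkpoints to 1.09 and T cell markers to 1.14. Matched on the Empty NP level, p53 targets moved to 91.27, MHC class I to 7.2, immune checkpoints to 0.73, T cell markers to 0.35, neutrophil markers to 80.73 and adipocyte markers to 94.93. From 2 low lists the number went to 4 with 10 bins and to 1 over members above 0, without overlap and on reads. From 7 high lists it went to 3 at a mean of 5 TPM or more, over members above 0 and on reads, and to 4 without overlap and matched on the Empty NP level. The cause was not tested. Lists near the limit also moved away from it. Over their settings T cell markers ran from percentile 0.35 to 41.85 and the interferon gamma response from 2.09 to 22.42. Immune checkpoints ran from 0.73 to 43.47 and dendritic cell markers from 0.10 to 61.73. Phosphatidylserine receptors ran from 42.07 to 99.26, heat shock proteins from 89.51 to 99.11, and hypoxia and glycolysis from 38.64 to 98.34. Of 54 other named genes, 8 changed sign when centred and 8 when rescaled (Apoe, Bsg, Dcn, H2-Ab1, Lyz2, Nptn, Tbp and Tmem30a in both). Of these, 2 were past 2-fold as deposited: Tmem30a went from -1.07 to 0.37 and 0.30, and H2-Ab1 from -1.18 to 0.26 and 0.01.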

Other observations

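Endothelial markers lay at percentile 20.8 by their median, while their pooled reads were 141 in Empty NP and 31 in FuOXP NP, 8.49-fold lower (5.72 to 13.0). Flt1, a receptor of vascular growth factors, made up most of them at 98 and 19 reads. Fibroblast markers lay at percentile 95.3, with 7 members above and 5 below the median gene. Dcn, a matrix proteoglycan, was at 54.7 and 42.1 TPM, 1.07 above the median gene, while Fbln2 and Col1a1, which encode matrix proteins, were 19.6-fold (4.79 to 172) and 12.4-fold (3.69 to 65.4) lower. Chemokines lay at percentile 24.3 by their median with 5 members above and 7 below the median gene, but at 92.1 with a pseudocount of 0.1 TPM and 93.0 after rescaling, and their pooled reads were 47 in both libraries, 1.87-fold lower (1.22 to 2.86), so the list had no stable direction relative to the typical gene. Ccl9 had 1 read in Empty NP and 15 reads in FuOXP NP, 8.04-fold higher (1.24 to 338). The type I interferon response and the cGAS-STING pathway, at percentiles 64.4 and 47.6, lay within the middle 95% of random lists, as did DNA repair at 85.1 and extracellular matrix genes at 55.8.

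Among genes used as references, Actb was 3.99-fold lower (3.23 to 4.94) and Pgk1 was 4.57-fold lower (2.67 to 8.12), against 3.20-fold for the typical gene with at least 50 reads. The reads of the whole reference list were 2.12-fold lower (1.96 to 2.29), and Tbp, named after its values were seen, alone held 899 of its 1397 reads in Empty NP and 966 of 1231 in FuOXP NP. The list lay at percentile 77.7, and at 14.9 without genes whose exons overlap another, an alternative chosen after seeing the data. Of 36 subunits of mitochondrial complex I, which all respiring cells use, 7 were listed at 0 in Empty NP and 4 in FuOXP NP. A 0 in this table is therefore no evidence that a transcript was absent.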
